A study of Rattus norvegicus with 4 samples.

How the data were processed

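The study measured RNA in single cells from the small intestine of male Sprague-Dawley rats, an outbred laboratory strain, after Roux-en-Y gastric bypass (RYGB) or a sham operation. There were 4 libraries, 1 for each of sham jejunum, sham ileum, RYGB alimentary limb and RYGB common limb. The labels do not say how many rats gave tissue to a library. Per the labels' protocols, tissue was minced, digested with enzymes under warming, strained to single cells and depleted of dead cells with magnetic beads before capture.

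The authors deposited 1 matrix of raw counts of unique molecular identifiers (UMIs, tags that count each captured RNA molecule 1 time), with 22050 genes and 34791 cell barcodes. All values were whole numbers and no normalization had been applied. The barcodes of each library carry a prefix that equals the description of exactly 1 sample, and this prefix assigned cells to libraries. The submitters' processing notes name FastQC, Cell Ranger 6.0.0, Seurat 3.1.2 and the genome build Rnor_6.0, with no role stated for each. The gene annotation is not given in the sources used here. Gene symbols are those of the deposited matrix, and no coordinates are given, since the annotation at hand describes another assembly. Of the genes, 4439 had no UMI in any kept cell. Every deposited barcode had at least 500 UMIs and at most 20.0% mitochondrial UMIs. No column of values from other samples was left over (0 unused).

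Cells were kept with at least 500 UMIs, at least 200 genes and at most 25% mitochondrial UMIs, which removed 12 barcodes. Doublets were called per library with Scrublet as implemented in scanpy 1.11.5. The automatic threshold marked 2.24% of sham jejunum and 2.23% of common limb cells. It marked 0 cells in the sham ileum and in the alimentary limb, so in these 2 libraries cells in the top 5% of scores were removed instead, which came to 4.47% and 4.72%. The difference in doublet rule between libraries can move shares of cell classes. After these steps 33557 cells were analysed.

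Counts were scaled to 10000 per cell and log-transformed. Clusters came from 2000 variable genes, 30 principal components without batch correction, 15 nearest neighbours and the Leiden algorithm at resolution 1 (leidenalg 0.10.2, igraph 0.11.9), over all libraries together. Genes of the fixed gene lists that were not cell type markers were left out of the variable genes. This gave 42 clusters of at least 10 cells. The other 9 analysed cells each stood alone and count as unnamed. A cluster took the name of the cell type whose fixed markers it held at the highest mean log ratio, with at least 3 markers at 2-fold or more. It stayed unnamed if its 10 leading genes held more markers of another type, or if it had no marker of its own type among those 10 and its median UMI count lay more than 3 times below the library median in every library that gave at least 20% of its cells. These numeric limits and the choices that follow were set after the clusters had first been seen. T cells and NK or innate lymphoid cells were merged, both kinds of endothelium were merged, and an epithelial name needed at least 2 pan-epithelial markers at 2-fold. Clusters 13, 18, 19, 27, 37 and 39 stayed unnamed, of which cluster 27 (259 cells, 241 of them from the alimentary limb) was led by Cd79b, Top2a and Birc5. All names are "-like", since no deposited annotation of cells was used.

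For each library and class, raw counts were summed over cells and scaled to a class total of 1000000 (CPM). With 1 library per group there is no replicate, no test was run and no p-value is given. CPM values carry exact 95% Poisson intervals, ratios of 2 libraries carry exact conditional binomial intervals and shares of cells carry exact Clopper-Pearson intervals. All of them cover counting error only, not the spread between animals or preparations. Those of CPM values and ratios treat each UMI as independent and also leave out the spread between cells of a library. Where a gene had 0 counts in 1 library, the ratio was bounded with 3 counts over that library's class total. For 30 gene lists, the median log2 CPM ratio was taken over members with at least 30 UMIs in the 2 libraries. Its percentile among 10000 random lists matched on mean expression describes these libraries and is not a test. A list member was called higher or lower when its CPM ratio was at least 1.5-fold and its counting interval excluded 1. Shares of cells with a UMI were compared after thinning each cell to 1000 UMIs, leaving out shallower cells.

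The comparisons, gene lists, cell type markers, filters, 19 alternatives and the rule for named genes were fixed before the data were examined. The rule names, for each comparison, Slc2a1, Prkci and Prkcz. It adds the 10 genes with the largest CPM ratio in each direction among genes at 50 CPM or more in the higher library, leaving out ribosomal, mitochondrial, immunoglobulin and T cell receptor genes. It also allows up to 2 members per list and direction that pass the 1.5-fold rule. The text uses the first 2 parts in full for all 4 comparisons, and the members of the lists it describes, a subset picked after the values had been seen. Genes outside the rule that the text names are members of the polarity or hexose transporter lists, members of the 2 lists plotted gene by gene, or cluster leaders and genes of other cell classes. Those were chosen after their values had been seen.

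The interval and calling code was tested on counts simulated from the real means and library sizes, with 200 genes set apart by known folds. All genes set 2-fold or 4-fold apart were recovered and 0% of the unchanged genes were called in each of the 4 comparisons. Counts were drawn with Poisson error alone and only genes at 50 CPM or more were assessed, so this outcome was largely set in advance. It checks the code and says nothing of genes on few UMIs or of the recovery of 1.5-fold changes. The 95% intervals of the 200 genes covered the true ratio for 96.0% in common limb against sham ileum (2114 genes), 93.0% in sham ileum against sham jejunum (2127 genes) and 96.5% in common limb against alimentary limb (2229 genes). For alimentary limb against sham jejunum (2205 genes) they covered 72.5% with the observed totals and 95.5% with the true totals. The simulated folds there moved the library total by 0.0204 on the log2 scale, which exceeds the counting error of abundant genes. That shift depends on which genes were drawn in the 1 simulated pair and is not a trait of this comparison. Intervals in all 4 comparisons leave out the uncertainty of the scaling, which matters most for abundant genes.

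The alternatives were other cell filters, doublets kept in, TMM factors (edgeR 4.0.16, R 4.3.3), median-of-ratios factors, equal weight per cell, all epithelial-like or all kept cells, Leiden resolutions 0.5 and 2, totals without the 20 most abundant genes, totals without mitochondrial and ribosomal genes, other count limits, sham jejunum as the reference for the common limb, and each library clustered on its own. The alternative with all deposited barcodes also kept doublet calls in. After seeing the data 2 alternatives were added. The first leaves out enterocyte-like clusters with a median under 2000 UMIs (clusters 5, 23 and 24) and the second leaves out those with over 95% of cells from 1 library (clusters 16, 23 and 24). The sample descriptions give both sham libraries the same number code and both RYGB libraries another, and the labels do not say what a code stands for. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.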

Results

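Small intestine of male rats was profiled by single-cell RNA sequencing after Roux-en-Y gastric bypass, an operation that joins a small gastric pouch directly to a limb of small bowel. The labels state that the study asked how atypical protein kinase C (aPKC) and the glucose transporter GLUT1, encoded by Slc2a1, take part in how the intestine handles glucose after the operation. Of the 4 libraries, sham jejunum had 8124 cell barcodes with 103723517 UMIs, sham ileum 8123 with 47069696, alimentary limb 10566 with 83776195 and common limb 7978 with 83756106. Median depths per barcode were 4257.5, 4772, 2811 and 3692 UMIs in that order. There was 1 library per group and no replicate, so each comparison below describes 2 libraries and all intervals cover counting error only.

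Enterocyte-like cells made up 42.5% of the sham jejunum (3371 of 7940 cells, 95% interval 41.4 to 43.6), 47.7% of the alimentary limb (4802 of 10065, 46.7 to 48.7) and 48.6% of the common limb (3789 of 7799, 47.5 to 49.7). In the sham ileum they were only 3.24% (251 of 7753, 2.85 to 3.66), and T, NK or innate lymphoid-like cells made up 84.0% of that library (83.2 to 84.8). Those lymphoid-like cells were 34.0%, 23.9% and 30.5% of sham jejunum, alimentary limb and common limb. Goblet-like cells were 1.20% of sham jejunum and 2.96% of the alimentary limb, mast-like cells 0.290% and 1.75%, and plasma-like cells 1.21% and 3.68%. Enteroendocrine-like cells were 0.567% of sham jejunum, 0.0994% of the alimentary limb, 0.142% of sham ileum and 1.62% of the common limb. Granulocyte-like cells were 3.01% of sham jejunum and 0.0199% of the alimentary limb. Unnamed cells made up 8.11%, 7.84%, 7.11% and 10.04% of sham jejunum, sham ileum, alimentary limb and common limb. Tissue digestion and the removal of dead cells can set such shares. With the stricter cell filter the enterocyte-like shares were 20.3%, 1.37%, 19.5% and 33.3% in the same order, and at Leiden resolution 0.5 that of the alimentary limb was 26.4%.

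**Figure D1:**
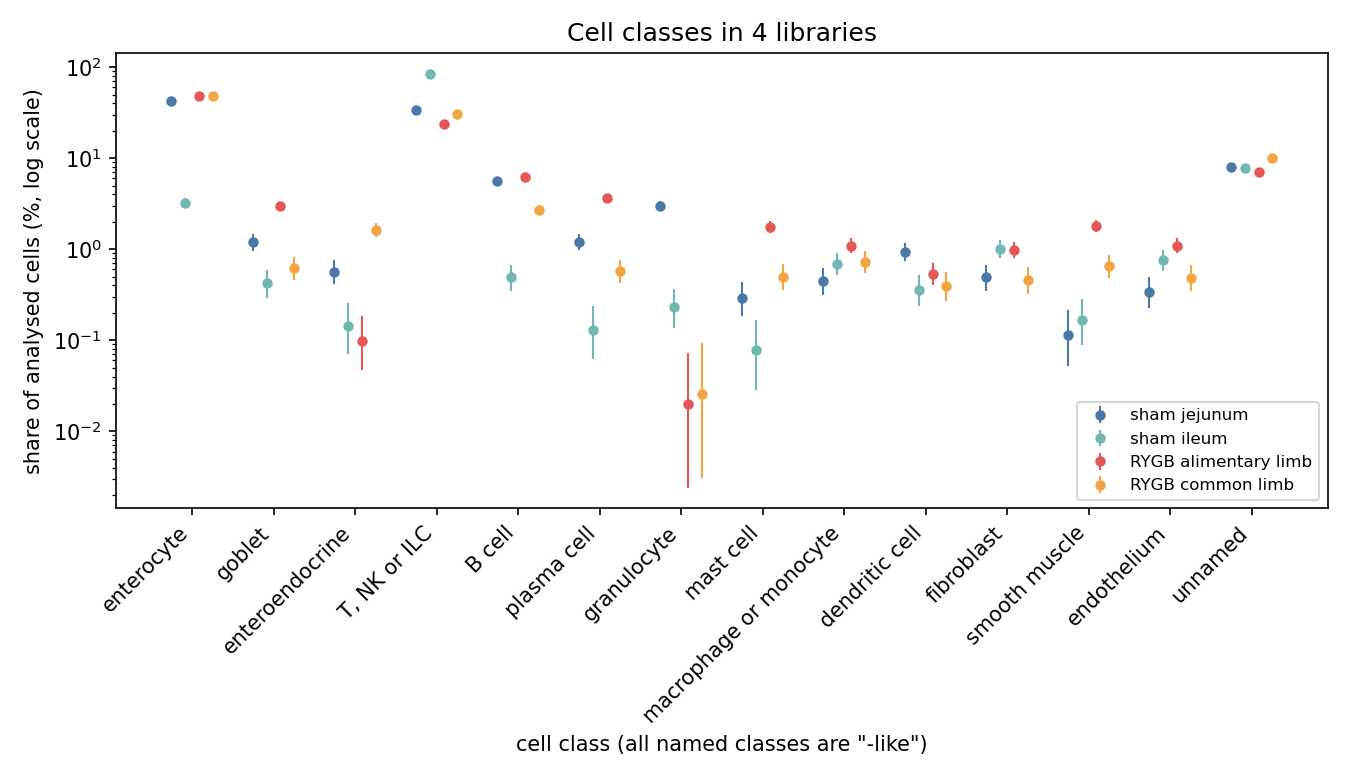
Share of analysed cells (percent, log axis) in each cell class for the 4 libraries, with points for the share and bars for the exact 95% binomial interval. Enterocyte-like cells were 3.24% of the sham ileum against 42.5% to 48.6% of the other libraries.

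The alimentary limb, joined to the gastric pouch and made from jejunum, was compared with sham jejunum in enterocyte-like cells. All 16 measured cholesterol synthesis genes were higher in the alimentary limb, with a median log2 ratio of 2.11, at percentile 100.0 of the random lists. Idi1, the isopentenyl diphosphate isomerase, was 7.86-fold higher (7.58 to 8.15), Fdps, the farnesyl diphosphate synthase, 7.10-fold (6.96 to 7.25) and Sqle, the squalene epoxidase, 6.09-fold (5.86 to 6.32). Fdft1, Msmo1 and Cyp51, which act in the steps from farnesyl diphosphate to cholesterol, were 5.51-fold, 5.34-fold and 5.10-fold higher. Pcsk9, whose product sends the LDL receptor to breakdown, stood at 9.44 against 0.538 CPM, 17.5-fold higher (13.0 to 24.2), a log2 ratio of 4.13 that was 3.13 over all epithelial-like cells. Fatty acid oxidation and PPAR alpha target genes were lower in 12 of 19 members and higher in 1, with a median of -0.61. Hmgcs2, the rate-limiting enzyme of ketone body synthesis, was 45.9-fold lower (27.7 to 82.4), and Slc27a2 was 32.7-fold lower on 2 against 92 UMIs (8.79 to 274). The log2 ratio of Slc27a2 was -5.03 and that of Hmgcs2 -5.52, against -1.71 for Slc27a2 under the stricter cell filter and -3.40 for Hmgcs2 with the mean over cells of per-cell shares. Angptl4 was the member that was higher, by 1.66-fold.

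Genes of nutrient uptake were mostly lower or within 1.5-fold in the alimentary limb. Amino acid and peptide transport had 5 of 13 members lower and 1 higher (10 and 1 with TMM or median-of-ratios scaling), with the peptide transporter Slc15a1 2.37-fold lower and Slc43a2 2.34-fold lower. Brush border digestion had 4 of 12 lower and 1 higher (7 and 1 with either scaling), among them the aminopeptidase Anpep, 3.84-fold lower, and Ggt1, 6.55-fold lower. Fat absorption had 4 of 18 lower and 0 higher, including the fatty acid binding protein Fabp1 at 4.34-fold (4.33 to 4.35) and the apolipoprotein Apoc2 at 4.17-fold. Other genes with the largest ratios on this side were Enpp7, an alkaline sphingomyelinase (8.77-fold lower), Anxa13 (5.65), Guca2a, which encodes guanylin (5.36), the nuclear receptor Nr0b2 (4.88), the gluconeogenic enzyme Pck1 (4.20), Tm4sf4 (4.14), Aldh1b1 (4.10) and Retsat (3.96). Iron and mineral handling had 6 of 13 members higher and 3 lower, but 2 higher and 4 lower with either scaling. The iron importer Slc11a2 was 1.95-fold higher and the calcium-binding S100g 1.93-fold higher. In glycolysis and lactate 10 of 21 members were higher and 1 lower (median 0.62), with the monocarboxylate transporter Slc16a1 4.44-fold higher and Ldhb 8.92-fold higher on 38 against 6 UMIs, a log2 ratio of 3.16 that was 1.76 without low-UMI clusters and 2.21 with doublet calls kept in.

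Immune-related transcripts were also higher in enterocyte-like cells of the alimentary limb. MHC class II presentation had 5 of 7 members higher and 0 lower (median 2.56), with RT1-Da 5.89-fold, Cd74 5.36-fold, RT1-Ba 7.53-fold and RT1-Bb 8.98-fold higher. The class II transactivator Ciita, at a log2 ratio of 0.551 (0.264 to 0.838), and Ctss, at 0.418 (0.319 to 0.517), were not called higher. Interferon response genes were higher in 9 of 16 (Ifit2 6.07-fold, Gbp5 4.56-fold) and in 5 of 16 with median-of-ratios scaling, and inflammatory cytokines in 9 of 16, such as Ccl2 at 6.44-fold and Ifng at 27.5-fold on 39 against 2 UMIs (7.11 to 235), whose log2 ratio of 4.78 was 2.43 with doublet calls kept in. Markers of B cells in these enterocyte-like cells stood at 16.5 against 2.09 CPM, of T cells at 38.0 against 10.2 CPM and of NK or innate lymphoid cells at 42.0 against 11.9 CPM. Carry-over of class II RNA was not tested for the alimentary limb, so the higher class II genes there may in part be RNA of immune cells. Goblet markers stood at 271 against 42.3 CPM, and the goblet genes Tff3 and Zg16 were 7.34-fold and 4.38-fold higher. Cell cycle genes were higher in 14 of 16 members (median 2.72), with Cdk1 at 102 against 7 UMIs (20.5-fold) and Ccna2 at 32 against 1 UMI (45.1-fold, 7.53 to 1836). Enteroendocrine hormones were lower in 5 of 8 members, with Gip 60.2-fold lower and Sst 11.7-fold lower. With the mean over cells of per-cell shares the log2 ratio of Gip was -4.02 in place of -5.91, that of Sst -1.80 in place of -3.55 and the hormone median -0.90 in place of -2.46, and over all epithelial-like cells Gip was at -10.06 and the median at -1.74. Enteroendocrine markers stood at 1.65 against 4.31 CPM and granulocyte markers at 0.428 against 14.7 CPM.

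Between these 2 libraries 48 genes at 50 CPM or more were at least 2-fold higher in the alimentary limb and 50 at least 2-fold lower. The class sat in different clusters, so these ratios do not separate cell make-up from expression within a cluster. Clusters 3, 8 and 4 held 50.04%, 30.7% and 16.1% of the jejunal enterocyte-like cells. Clusters 5, 4, 8 and 3 held 36.4%, 29.6%, 14.0% and 11.7% of those of the alimentary limb. Clusters 5, 23 and 24, which were low in UMIs, made up 44.7% of the class there and 2.91% in sham jejunum, and without them the log2 ratio of Tff3 was 1.18 in place of 2.88, that of Zg16 0.84 in place of 2.13, that of Gbp5 1.51 in place of 2.19, that of Ccl2 2.05 in place of 2.69 (4.03 under the stricter cell filter), that of Cdk1 1.59 in place of 4.36, that of Ccna2 2.59 in place of 5.49, the median of the MHC class II list 1.80 in place of 2.56 and the cell cycle median 0.69 in place of 2.72. The cell cycle median was also 0.69 at Leiden resolution 0.5 and 1.28 at Leiden resolution 2. TMM and median-of-ratios scaling moved all log2 ratios of this comparison by -0.24 and -0.27, and the counts of genes at least 2-fold higher and lower became 32 and 75 with TMM and 27 and 80 with median of ratios. With the mean over cells of per-cell shares they became 125 and 51.

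The 3 genes closest to the study's question differed little between alimentary limb and sham jejunum. Slc2a1 stood at 6.80 CPM (413 UMIs, 6.16 to 7.49) against 5.90 CPM (505 UMIs, 5.40 to 6.44), a log2 ratio of 0.20. This ratio was -0.04 with TMM, -0.07 with median-of-ratios scaling and -0.53 with the stricter cell filter. It was 0.54 with the mean over cells of per-cell shares. Prkci, which encodes aPKC iota, was 1.18-fold higher (1.09 to 1.29). Its log2 ratio of 0.24 was -0.03 with median-of-ratios scaling and 0.39 with the mean over cells of per-cell shares. Prkcz, which encodes aPKC zeta, stood at 41.3 against 41.7 CPM. None of the 12 measured polarity complex genes reached 1.5-fold, and their median of 0.09 was -0.15 with TMM and -0.19 with median-of-ratios scaling. Hexose transporters went both ways, with 3 of 10 higher and 4 lower, which became 2 and 4 with TMM, 0 and 4 with median of ratios and 2 and 2 under the stricter cell filter. The apical sodium-glucose transporter Slc5a1 was 1.80-fold higher (465 against 258 CPM) and the glucose transporter Slc2a2 (GLUT2) 1.80-fold higher (537 against 299 CPM). The log2 ratios of Slc5a1 and Slc2a2 were 0.85 and 0.85, and 0.58 and 0.57 with median of ratios. Slc2a8 was 1.71-fold higher, and Slc2a9 was 1.98-fold, Slc5a4 1.89-fold, Slc5a9 1.58-fold and Slc5a11 1.51-fold lower. G6pc, the glucose-6-phosphatase, was 2.498-fold higher.

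**Figure D2:**
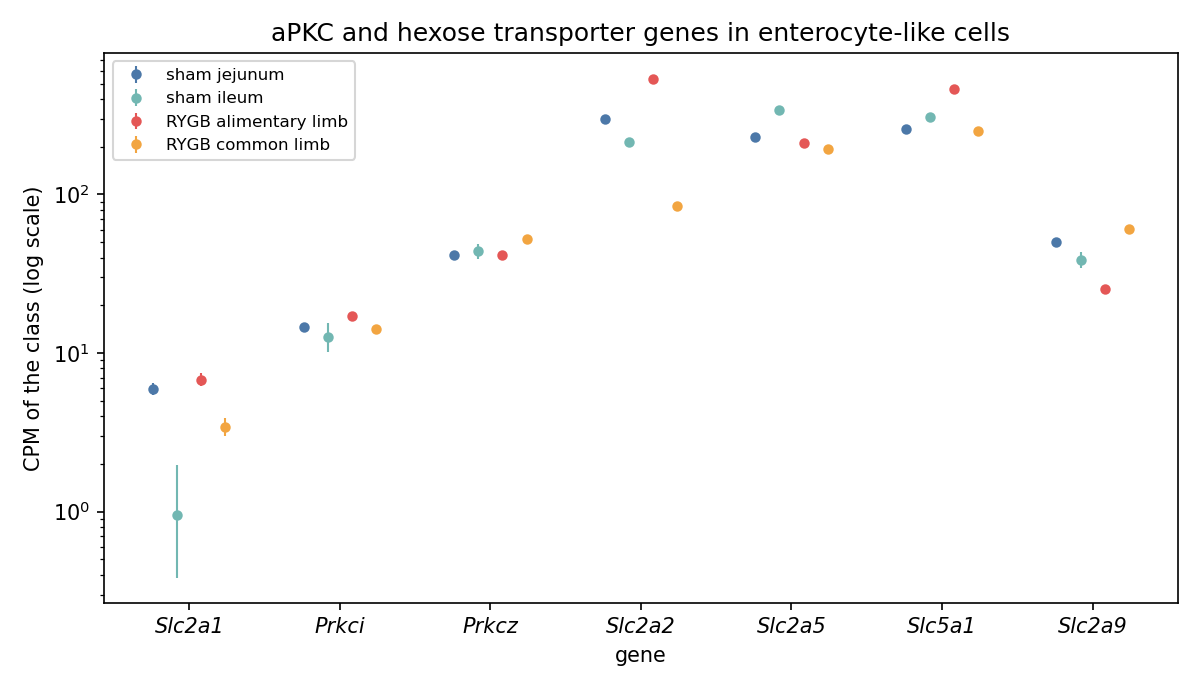
CPM (log axis) of 7 aPKC and hexose transporter genes in enterocyte-like cells of the 4 libraries, with points for the value and bars for the exact 95% Poisson interval. Slc2a1 lay between 0.954 and 6.80 CPM, while Slc2a2 and Slc5a1 reached 537 and 465 CPM in the alimentary limb.

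The common limb lies below the junction of both limbs and was compared with the sham ileum. In its enterocyte-like cells antimicrobial, interferon and antigen presentation genes were higher. Antimicrobial and mucosal defence had 5 of 8 members higher and 0 lower (median 3.08), with the lectin Reg3b 12.8-fold higher (11.7 to 14.2), the oxidase Duox2 38.0-fold on 736 against 2 UMIs (10.5 to 315) and the nitric oxide synthase Nos2 37.1-fold on 359 against 1 UMI (6.62 to 1469). Interferon response had 13 of 17 members higher and 0 lower, such as Ifit2 at 31.2-fold on 302 against 1 UMI (5.56 to 1237) and Mx2 at 13.7-fold on 397 against 3 UMIs (4.65 to 66.6). MHC class II presentation had 6 of 7 members higher and 0 lower (median 2.29), with RT1-Db1 6.94-fold (6.53 to 7.38), RT1-Ba 5.21-fold and the class II transactivator Ciita 21.0-fold on 611 against 3 UMIs (7.17 to 102). Beside them, NK or innate lymphoid markers in enterocyte-like cells stood at 41.1 against 292 CPM, T cell markers at 17.6 against 42.9, B cell markers at 2.34 against 11.04 and plasma cell markers at 562 against 435 CPM. Markers of secretory cells were higher, with Paneth markers at 6.28 against 1.499 CPM and goblet markers at 32.3 against 13.8 CPM.

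Other genes with the largest ratios on the high side of the common limb were the complement component C3 (29.2-fold, 18.0 to 51.2), the phospholipase Pla2g4c (25.7-fold), Lypd8 (6.76), Cd59 (6.60), the carbonic anhydrase Ca4 (6.22), Gmds (5.98) and Mgst1 (5.36). Without clusters held mostly by 1 library the log2 ratio of Mgst1 was 0.85 in place of 2.42 and that of Lypd8 1.82 in place of 2.76, and over all epithelial-like cells that of Gmds was 1.08 in place of 2.58. On the low side were Cd7 (12.5-fold lower), Cyp1a1 (11.9), Bmp2 (9.05), Ano6 (7.07), the chemokine Ccl5 (6.28), Cpm (6.04), Asah2 (5.64), Fam151a (5.18), Ifitm1 (5.08) and Nr4a2 (4.63). Cd7 and Ccl5 are genes of lymphoid cells, whose markers were also lower, and with the mean over cells of per-cell shares the log2 ratio of Cd7 was -2.36 in place of -3.64, that of Ccl5 -1.35 in place of -2.65 and that of Ifitm1 -0.92 in place of -2.35. Endoplasmic reticulum stress genes were higher in 5 of 14 members and lower in 1 (1 and 2 over all epithelial-like cells), with the chaperones Pdia6 and Sdf2l1 2.73-fold and 2.67-fold higher, log2 ratios of 1.45 and 1.42 that were 0.50 and 0.10 over all epithelial-like cells. The pentose phosphate pathway was higher in 4 of 6 members and lower in 0. Jejunal identity genes were lower in 5 of 6 and fat absorption genes in 7 of 17 (3 of 17 with TMM or over all epithelial-like cells), with Gata4 9.68-fold (19 against 19 UMIs at unequal totals), the lactase Lct 2.74-fold, Apoa1 2.05-fold and Apoa4 1.94-fold lower. Crypt stem cell genes were lower in 6 of 7, among them Cd44 (4.55-fold) and Olfm4, at least 342-fold lower on 0 against 106 UMIs, where the 106 UMIs came from only 251 sham ileum cells. The crypt stem cell median of -1.64 was -0.36 under the stricter cell filter, where 3 members were measured, and -2.48 over all epithelial-like cells. Under the stricter cell filter the log2 ratio of Cd44 was 0.17 in place of -2.18 and that of Pcsk9 0.54 in place of -1.45, both of the opposite sign. Cholesterol synthesis genes had 5 of 16 members lower and 1 higher (median -0.49), with Hmgcs1 2.72-fold and Pcsk9 2.73-fold lower and Dhcr7 1.91-fold higher. The direction turned against sham jejunum, where the median was 0.72 and the log2 ratios of Hmgcs1, Pcsk9 and Dhcr7 were 0.64, 0.27 and -1.04. Over all kept cells, where cell make-up enters the ratio, the median was 0.97 and Hmgcs1 at 0.56.

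For the genes of the study's question, Slc2a1 stood at 3.42 CPM (243 UMIs) in the common limb and 0.954 CPM in the sham ileum, the latter on 7 UMIs, a ratio of 3.59-fold (1.71 to 9.02). Its log2 ratio of 1.84 was 0.19 over all epithelial-like cells, 0.48 without clusters held mostly by 1 library, -2.10 over all kept cells and -0.79 against sham jejunum. Prkci stood at 14.2 against 12.5 CPM (1.13-fold, 0.916 to 1.42) and Prkcz at 52.6 against 43.9 CPM (1.20-fold, 1.07 to 1.35). Of 12 polarity complex genes, Pard3b was 1.82-fold higher, the scaffold Sqstm1 1.92-fold lower and 10 stayed within the rule. Hexose transporters were lower in 5 of 9 members and higher in 2, with Slc2a2 2.52-fold, the fructose transporter Slc2a5 1.77-fold, Slc5a4 1.97-fold, Slc5a11 1.52-fold and Slc2a6 80.6-fold lower (6 against 50 UMIs, a log2 ratio of -6.33 that was -4.26 under the stricter cell filter) and Slc2a9 1.56-fold higher. Slc2a6 was a leading gene of unnamed cluster 39, which had 19 of its 26 cells from the sham ileum. Other leading genes of that cluster went both ways, with Cyp1a1 lower and Reg3b and Pla2g4c higher in the common limb. Carry-over from that cluster was not tested. G6pc was 6.65-fold lower and Fbp1 2.18-fold lower.

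In this comparison 66 genes at 50 CPM or more were at least 2-fold higher and 70 at least 2-fold lower, the latter 106 with totals without the 20 most abundant genes. Cluster 1 held 221 of the 251 sham ileum cells and 66.2% of the common limb cells, while clusters 16 and 24 held 22.2% and 10.3% of the common limb cells and few others. Under the stricter cell filter the log2 ratio of Nos2 was 1.94 in place of 5.21, that of Duox2 3.14 in place of 5.25, that of Ifit2 2.14 in place of 4.96 and that of Mx2 1.94 in place of 3.77. The antimicrobial median was 0.20 over all epithelial-like cells. Against sham jejunum that list had 4 of 12 members higher and 4 lower, with a median of 0.18. With the same reference the log2 ratio of Reg3b was -0.09 and that of Mgst1 -4.11.

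**Figure D3:**
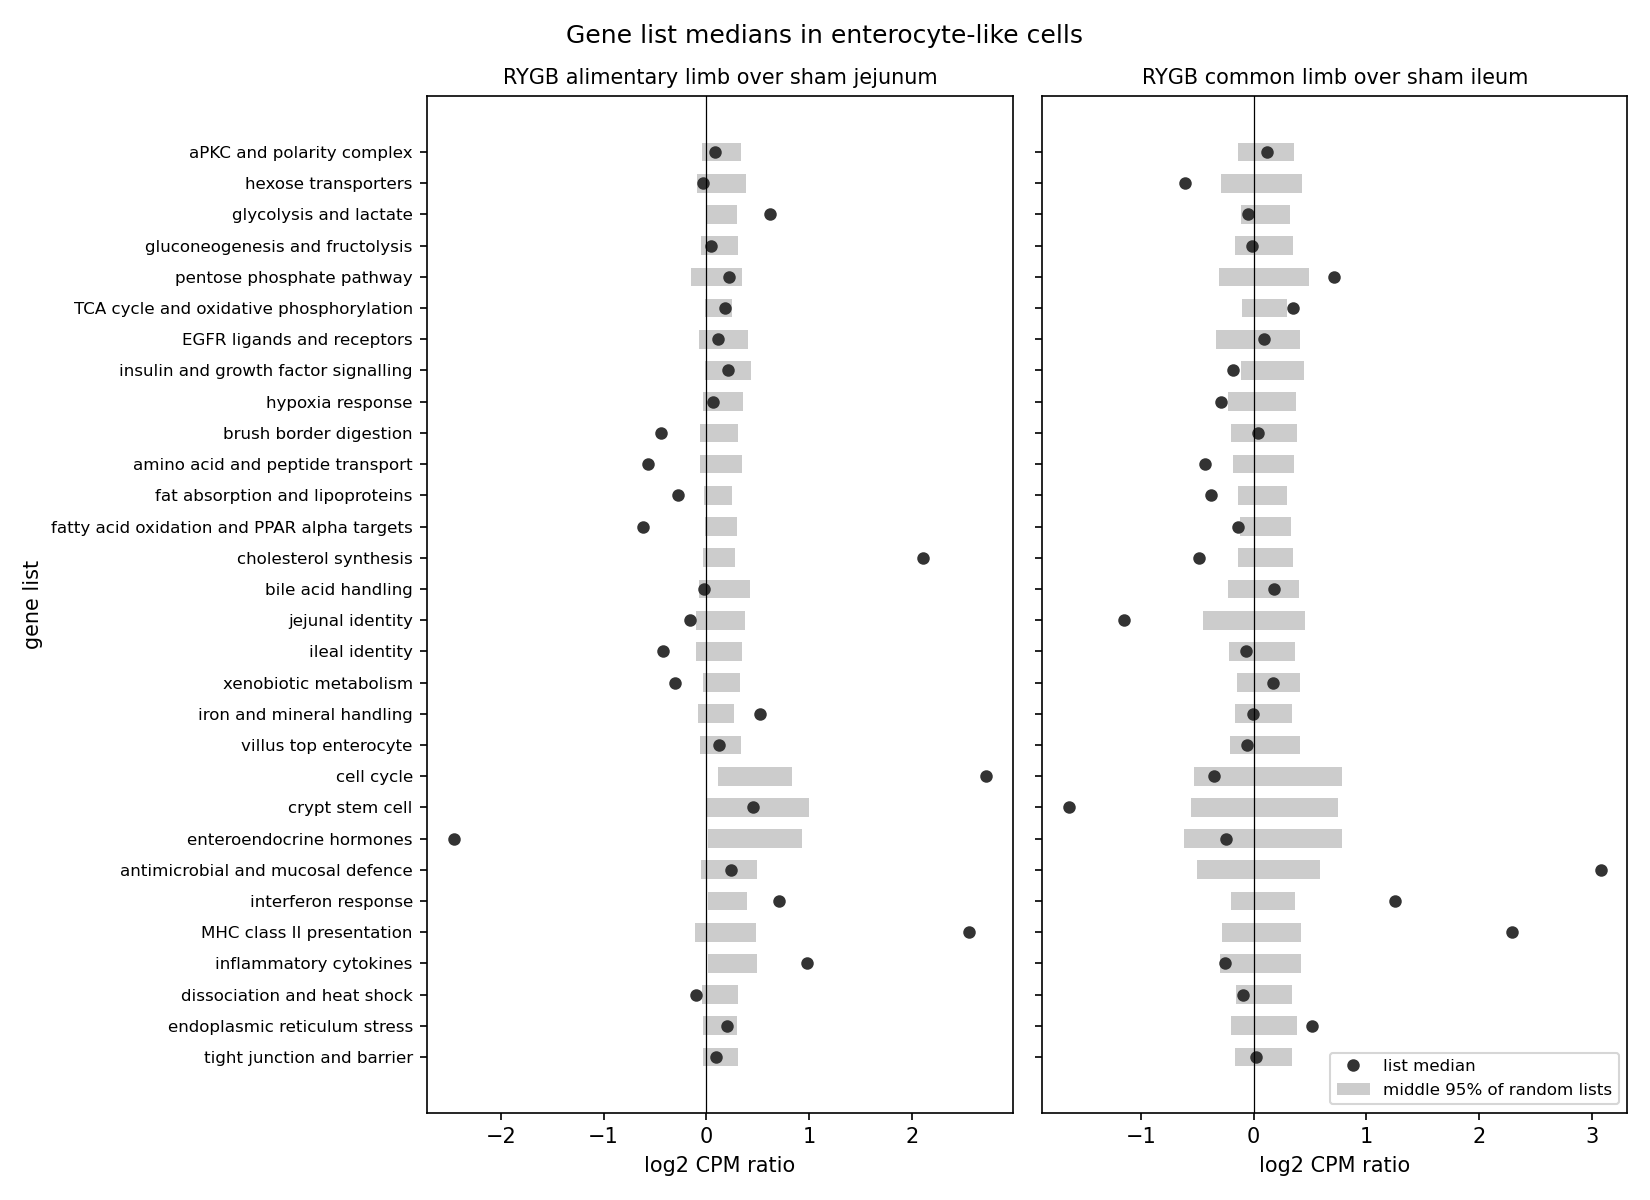
Median log2 CPM ratio of each of 30 gene lists (points) with the middle 95% of matched random lists (grey bars), for alimentary limb over sham jejunum and for common limb over sham ileum. The cholesterol synthesis median was 2.11 in the first and -0.49 in the second, and that of MHC class II presentation 2.56 and 2.29. Carry-over of class II RNA was not tested for the alimentary limb.

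**Figure D4:**
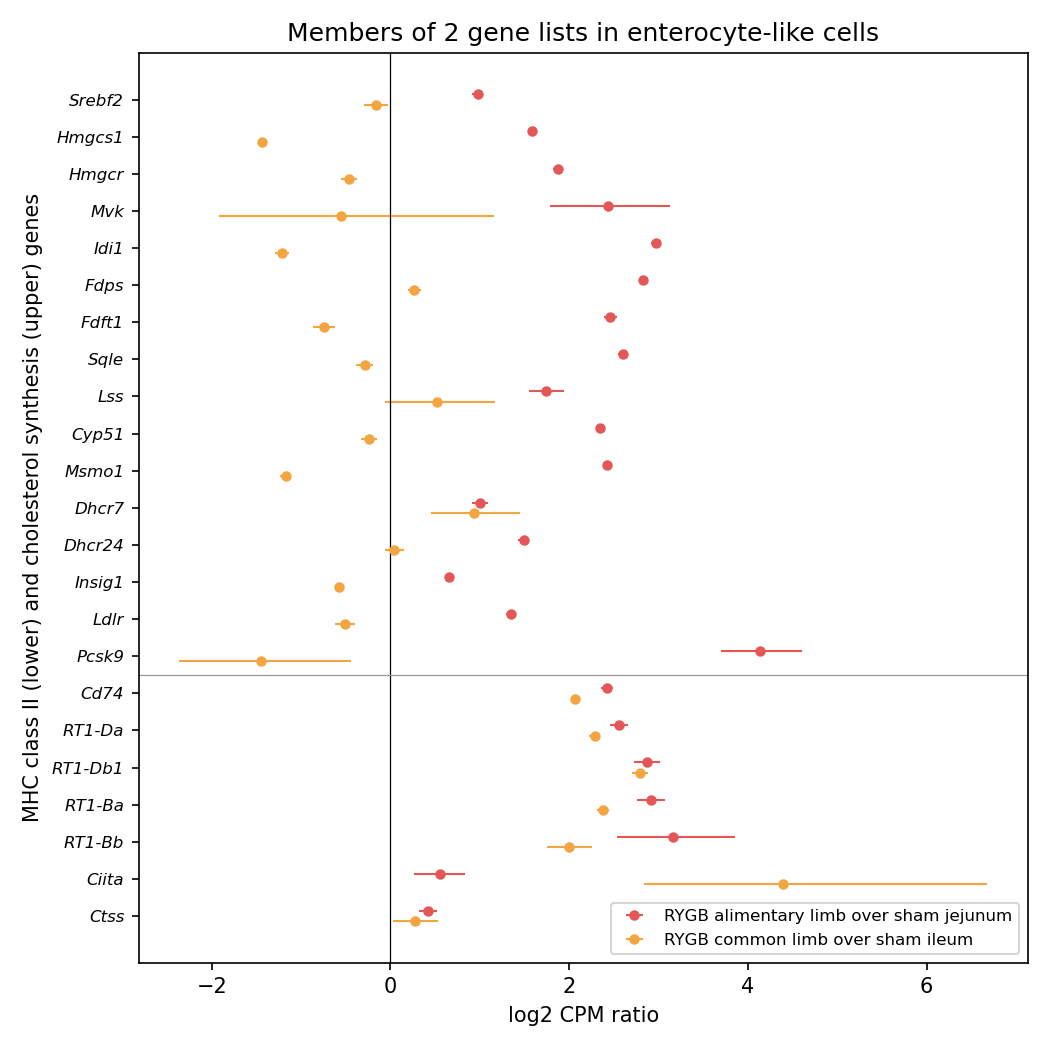
Log2 CPM ratio (points) with exact 95% counting intervals (bars) for each measured gene of the cholesterol synthesis and MHC class II lists in both comparisons. All 16 cholesterol synthesis genes lay above 0 in the alimentary limb, from 0.65 for Insig1 to 4.13 for Pcsk9. Ciita lay at 0.551 (0.264 to 0.838) in the alimentary limb and at 4.395 (2.841 to 6.677) in the common limb.

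Sham ileum and sham jejunum, compared to give the scale of a segment difference without bypass, stood much further apart. In enterocyte-like cells 374 genes at 50 CPM or more were at least 2-fold higher in the ileum and 569 at least 2-fold lower. Ileal identity genes were higher in 10 of 11 members (median 2.45) and bile acid handling genes in 6 of 9. The ileal bile acid binding protein Fabp6 was 1627-fold higher (1583 to 1673), the bile acid importer Slc10a2 309-fold (208 to 481) and Fgf19, the enterocyte hormone of bile acid feedback, at least 715-fold on 184 against 0 UMIs. Suox (728-fold), Cyp1a1 (403), Napsa (344), Ubd (177), Tst (125), Prss23 (111), Ccl20 (103) and RT1-Ba (57.1) were further genes with the largest ratios. Jejunal identity genes were lower in 4 of 8 members and higher in 0, with the folate transporter Slc46a1 72.8-fold lower on 1 against 848 UMIs (13.0 to 2877) and Lct 57.6-fold lower. Over all epithelial-like cells the log2 ratio of Suox was 6.56 in place of 9.51 and that of Prss23 5.37 in place of 6.79. That of Napsa was 6.78 in place of 8.42 with doublet calls kept in, that of Cyp1a1 7.29 in place of 8.65 with per-cell shares and that of Slc46a1 -3.22 in place of -6.18 under the stricter cell filter.

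Aadac was 1538-fold lower in the sham ileum on 2 against 35843 UMIs (426 to 12697). The lipoprotein receptor Scarb1 (445-fold, 2 against 10385 UMIs, 123 to 3679), the carotene oxygenase Bco1 (445), Gsta2 (135), Mgst1 (92.5), the antibody transporter Pigr (90.9) and Enpp3 (89.6) were also lower, and Gsta3 and Slc37a2 were at least 822-fold and 142-fold lower. Over all epithelial-like cells the log2 ratio of Pigr was -3.56 in place of -6.51 and that of Scarb1 -7.29 in place of -8.80, and without clusters held mostly by 1 library that of Enpp3 was -8.60 in place of -6.49. Antimicrobial genes were lower in 6 of 10 (median -4.02, and -1.91 over all epithelial-like cells), TCA cycle and oxidative phosphorylation in 18 of 21 (Ndufa4 6.40-fold, Mdh2 4.77-fold) and glycolysis in 14 of 18. Cholesterol synthesis genes were higher in 13 of 16 (Idi1 5.94-fold, Msmo1 5.47-fold) and MHC class II genes in 5 of 7. Immune markers in enterocyte-like cells were higher as well, with B cell markers at 11.04 against 2.09 CPM, T cell markers at 42.9 against 10.2 and NK or innate lymphoid markers at 292 against 11.9, and carry-over of class II RNA was not tested for this comparison. Dissociation and heat shock genes were higher in 13 of 15 (Hspb1 15.7-fold, Fosb 3.61-fold). Slc2a1 was 6.19-fold lower in the ileum on 7 against 505 UMIs (2.98 to 15.5), a log2 ratio of -2.63 that was -1.02 over all epithelial-like cells and 1.59 over all kept cells, with Prkci 1.16-fold lower (0.935 to 1.45) and Prkcz 1.05-fold higher (0.936 to 1.18). Totals without the 20 most abundant genes moved all log2 ratios by 0.15, and the counts of genes at least 2-fold higher and lower became 564 and 566. Cluster 1 held 221 of the 251 ileal cells but 0 jejunal ones.

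In the common limb against the alimentary limb, the comparison of both limbs after bypass, 303 genes were at least 2-fold higher and 547 at least 2-fold lower. Ileal identity genes were higher in 10 of 11 (median 2.98) and jejunal identity genes lower in 7 of 8. Fabp6 was 1596-fold, Prss23 1207-fold, Tst 850-fold, Suox 710-fold, C3 430-fold, Slc7a15 264-fold, Ubd 208-fold, Slc5a12 109-fold, Slc10a2 105-fold and Cyp2c24 102-fold higher. The log2 ratios of Prss23, Tst and Suox were 10.24, 9.73 and 9.47, and 7.49, 6.88 and 6.65 over all epithelial-like cells. Scarb1 was 1001-fold, Enpp3 698-fold, the jejunal transcription factor Gata4 258-fold, Gsta3 235-fold, Papss2 174-fold, Lct 171-fold, Aadac 114-fold, Bco1 97.9-fold, Kcne3 67.0-fold and Gsta2 59.2-fold lower. Without clusters held mostly by 1 library the log2 ratio of Aadac was -9.05 in place of -6.83 and that of Kcne3 -7.15 in place of -6.07.

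Glycolysis and lactate genes were lower in 15 of 19 members in the common limb (median -1.53), with Pkm 9.81-fold and Ldha 7.12-fold lower, while the hexokinase Hk2 was 6.36-fold higher. Cholesterol synthesis genes were lower in 13 of 16 and cell cycle genes in 15 of 16, and the cell cycle median of -2.57 was -1.09 without the low-UMI clusters. Dissociation and heat shock genes were higher in 12 of 15 (median 1.11). In enterocyte-like cells of the common limb goblet markers stood at 32.3 against 271 CPM, crypt progenitor markers at 22.5 against 86.4, B cell markers at 2.34 against 16.5 and plasma cell markers at 562 against 231 CPM. MHC class II genes were higher in 6 of 7 (median 4.67, and 2.69 with the mean over cells of per-cell shares) and interferon response genes in 11 of 17, with 3 of the latter lower. Slc2a1 was 1.99-fold lower in the common limb (1.69 to 2.34), and its log2 ratio of -0.99 was -3.11 without clusters held mostly by 1 library. Much of the Slc2a1 of the common limb therefore lay in clusters 16 and 24, with 840 and 390 common limb cells. Prkci was 1.21-fold lower and Prkcz 1.27-fold higher. Of 12 polarity complex genes, Mpp5 (2.10-fold), Sqstm1 (1.77-fold) and Pard6b (1.56-fold) were higher and 0 were lower. Hexose transporters were lower in 6 of 10 members and higher in 1 (median -0.94). Slc2a2 was 6.31-fold, Slc5a4 6.32-fold, Slc5a1 1.84-fold and Slc2a8 28.5-fold lower, the last on 3 against 73 UMIs, while Slc2a9 was 2.40-fold higher. Clusters 1, 16 and 24 held nearly all enterocyte-like cells of the common limb and 2 of those of the alimentary limb. TMM and median-of-ratios scaling moved all log2 ratios of this comparison by 0.23 and 0.25, and the counts of genes at least 2-fold higher and lower became 420 and 396 with TMM and 434 and 382 with median of ratios. Totals without the 20 most abundant genes moved them by 0.16 and totals without mitochondrial and ribosomal genes by -0.11.

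Across cell classes Slc2a1 was more abundant in lymphoid-like than in enterocyte-like cells of every library. In T, NK or innate lymphoid-like cells it stood at 15.1, 28.9, 18.6 and 20.7 CPM in sham jejunum, sham ileum, alimentary limb and common limb. After thinning to 1000 UMIs, 0.632% of enterocyte-like cells had a Slc2a1 UMI in sham jejunum, 0.810% in the alimentary limb and 0.273% in the common limb. In the sham ileum it was 0 of 249 cells (95% interval up to 1.47%), although the class had 7 Slc2a1 UMIs before thinning. Unthinned shares were 11.6%, 7.06%, 4.33% and 2.39% in these libraries, and thinning left out 46, 727, 123 and 2 cells. The lymphoid-like shares after thinning were 1.94%, 1.99%, 2.13% and 2.73% in the same order. Median depths were 23467, 8691, 16566 and 29675 UMIs in enterocyte-like cells and 2433, 2586, 2569.5 and 4837 UMIs in lymphoid-like cells. The enterocyte-like shares lay below the lymphoid-like ones, so shares alone do not separate expression in these cells from free RNA. Carry-over at the rate of T cell markers allowed 0.694%, 2.15% and 2.03% of the Slc2a1 CPM in enterocyte-like cells of sham jejunum, alimentary limb and common limb, and 60.1% in the sham ileum.

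Prkcz was detected differently. Its thinned shares in enterocyte-like cells were 4.15%, 3.31%, 5.37% and 3.21% in sham jejunum, alimentary limb, common limb and sham ileum, against 0.777%, 0.605%, 0.620% and 0.556% in lymphoid-like cells. Unthinned, they were 61.8%, 32.5%, 54.0% and 64.1%. Prkci had 1.74%, 1.74%, 1.42% and 0.803% in enterocyte-like cells against 1.01%, 0.821%, 0.443% and 1.02% in lymphoid-like cells, so its share in the sham ileum lay below that of lymphoid-like cells. Unthinned shares of Prkci in enterocyte-like cells were 28.9%, 17.1%, 21.5% and 26.3%. Slc2a3 had 0 UMIs in enterocyte-like cells of all 4 libraries.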

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

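All tests below were chosen as tests only after the results they weigh had been seen, although the scalings they draw on were among the alternatives fixed before the data were examined. Only the prediction on a cluster found nearly only in the common limb was written before the value of its own test was known. The carry-over tests of the class II genes and of Slc2a1 replaced first versions whose values had been seen.

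Results that ran in opposite directions in the 2 limbs are listed here, each as a log2 ratio of the limb to its sham segment in enterocyte-like cells. Only list medians and genes of the polarity and hexose transporter lists were screened, so other genes with opposite directions, such as G6pc, are not listed. The cholesterol synthesis median was 2.11 in the alimentary limb and -0.49 in the common limb. Slc2a2 was at 0.85 (0.57 with median-of-ratios scaling, under the 1.5-fold rule) and -1.33, and Slc2a9 at -0.98 and 0.64, in the same order. The opposite directions did not hold throughout, since the cholesterol synthesis median of the common limb was 0.72 against sham jejunum. Over all kept cells that median was 0.97 and Slc2a2 of the common limb was at 1.00. There the ratio also takes in cell make-up, with 3789 of 7799 common limb cells enterocyte-like and 251 of 7753 sham ileum cells. Those 2 values therefore do not by themselves decide the direction within enterocyte-like cells. With 1 library per group the difference was not tested.

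The higher cholesterol synthesis genes of the alimentary limb were weighed against 3 technical explanations. If a few abundant genes had set the scale, another scaling would have lowered the median, and the lowest median over 4 other scalings was 1.84. Another scaling moves all log2 ratios of the comparison alike, here by -0.27 at the lowest, with median of ratios. This result therefore shows only that the shift was small beside the median. If cells of low depth had carried the signal, it would have been lost without the low-UMI clusters, where the median was 2.12. In the alimentary limb those clusters held 2146 of 4802 cells at a median of 1291 UMIs, while the class held 60707900 UMIs. Cells this shallow weigh little in a sum, so a median of well-counted genes could hardly have moved. The value shows only that the difference was present in the deeper cells. RNA carried over from T, NK or innate lymphoid-like cells would need these genes to be abundant there. Their median log2 ratio of CPM in that class over enterocyte-like cells was -2.65, with 16 of 16 genes below 0. B-like and goblet-like cells were not tested as sources, though their markers were also higher in enterocyte-like cells of this limb. Of the 3 results, only the last speaks against its explanation, carry-over from T, NK or innate lymphoid-like cells. The mix of enterocyte-like cells was not weighed. Cluster 3 held 50.04% of the class in sham jejunum and 11.7% in the alimentary limb, and cluster 4 held 16.1% and 29.6%. The ratios therefore do not separate this mix from expression within a cluster. A difference between the animals or the preparations cannot be told from the operation with 1 library each.

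The MHC class II genes of the common limb stood at 9367 CPM in sum over 7 genes, against 2037 CPM in the sham ileum, an excess of 78.3% of the value. RNA of B cells, macrophages or dendritic cells was bounded by the least carried-over marker of each class, Cd79b (0.0759%), C1qa (0.0150%) and Cd83 (1.35%), and allowed 10.5% of the value. Without the clusters held nearly only by the common limb the list median was 2.43, close to the 2.29 of all enterocyte-like cells. Both results speak against these explanations. The labels name the operation of each library, and 1 library per group cannot separate its effect from differences between animals.

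Slc2a1 in enterocyte-like cells was weighed against RNA carried over from T, NK or innate lymphoid-like cells, in which it was more abundant. Carry-over of T cell markers allowed at most 2.15% of the observed Slc2a1 CPM in sham jejunum, alimentary limb and common limb, which speaks against that source in these 3 libraries. In the sham ileum it allowed 60.1%, or 0.573 CPM of 0.954 CPM observed (0.384 to 1.97), so the test cannot tell there. The ratio of common limb to sham ileum for Slc2a1 therefore rests on a reference value that carry-over could largely make up. Such carry-over would make the ratio too low rather than too high. The ratio also depended on the cells used. Its log2 value of 1.84 was 0.48 without clusters held mostly by 1 library and 0.19 over all epithelial-like cells. The ratio of common limb to alimentary limb also fell without those clusters. Much of the Slc2a1 of the common limb therefore lay in clusters 16 and 24 and was not spread over its enterocyte-like cells at large. No biological explanation was tested.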

How the results depend on the processing

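The alternatives without low-UMI clusters and without one-library clusters were chosen only after the main results had been seen, and all others before the data were examined. No paired analysis was possible because each group has 1 library and no test was run. The sample descriptions give both sham libraries the same number code and both RYGB libraries another, and the labels do not say whether a code marks an animal. With 1 library per group no threshold of a test applies, so a gene ratio counts as kept when it stayed within its counting interval. Of 156 gene ratios, 140 were kept with all deposited barcodes, which also keeps doublet calls in, 139 at Leiden resolution 0.5, 147 at Leiden resolution 2, 96 with TMM, 102 with median of ratios, 136 without low-UMI clusters, 112 without one-library clusters and 26 with all kept cells. Only 62 of 155 were kept under the stricter cell filter, where 1 gene gave no value, and 83 of 156 with the mean over cells of per-cell shares. The direction was the same for 155, 154 and 144 gene ratios with TMM, median of ratios and all kept cells, and for 151 of 155 under the stricter cell filter. Of 120 list medians the direction was the same for 105 with TMM, 106 with median of ratios, 116 without low-UMI clusters and 89 with all kept cells. Genes with at most 3 UMIs in both libraries were left out. Depth limits the sham ileum most, where 1 UMI in enterocyte-like cells is 0.136 CPM and 3 UMIs are 0.409 CPM. The values that follow moved or turned under an alternative, and the cause was not tested. Ratios over all kept cells also take in the cell make-up of each library, in which the sham ileum stood apart.

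With all kept cells, the counts of genes at least 2-fold apart were 89 higher for alimentary limb over sham jejunum, 918 higher and 965 lower for common limb over sham ileum and 1049 higher and 988 lower for sham ileum over sham jejunum. Log2 ratios of alimentary limb over sham jejunum were -0.13 for Prkcz and 0.20 for dissociation and heat shock, and log2 ratios of common limb over sham ileum were -2.10 for Slc2a1, 1.91 for Prkcz, 1.00 for Slc2a2, 1.23 for Fbp1, -0.45 for Ifit2, 1.32 for Apoa1, 1.40 for Apoa4, 0.56 for Hmgcs1, 0.74 for Lct, -0.0372 for Pdia6, -0.80 for Sdf2l1, 1.20 for hexose transporters, 1.37 for amino acid and peptide transport, 1.72 for fat absorption and lipoproteins, 1.29 for fatty acid oxidation and PPAR alpha targets, 0.97 for cholesterol synthesis, 0.87 for jejunal identity and -0.15 for endoplasmic reticulum stress, and log2 ratios of sham ileum over sham jejunum were 1.59 for Slc2a1, -1.45 for brush border digestion, -0.23 for cholesterol synthesis and -0.19 for bile acid handling. With median of ratios, the counts of genes at least 2-fold apart were 27 higher and 80 lower for alimentary limb over sham jejunum, and log2 ratios of alimentary limb over sham jejunum were -0.0694 for Slc2a1, -0.0316 for Prkci and -0.29 for Prkcz. With the mean over cells of per-cell shares, the counts of genes at least 2-fold apart were 125 higher for alimentary limb over sham jejunum, and log2 ratios of alimentary limb over sham jejunum were 0.54 for Slc2a1, 0.39 for Prkci, -0.16 for Prkcz and 0.37 for dissociation and heat shock. Log2 ratios of common limb over sham ileum were 0.0753 for insulin and growth factor signalling, and log2 ratios of common limb over alimentary limb were -0.57 for inflammatory cytokines. With a limit of at least 10 CPM, the counts of genes at least 2-fold apart were 133 higher and 91 lower for alimentary limb over sham jejunum, 171 higher and 180 lower for common limb over sham ileum, 704 higher and 1115 lower for sham ileum over sham jejunum and 530 higher and 1076 lower for common limb over alimentary limb. With no CPM filter, the counts of genes at least 2-fold apart were 2912 higher and 1085 lower for alimentary limb over sham jejunum, 784 higher and 4063 lower for common limb over sham ileum, 5158 higher and 2137 lower for sham ileum over sham jejunum and 1839 higher and 4171 lower for common limb over alimentary limb. With sham jejunum as reference in place of sham ileum, the counts of genes at least 2-fold apart were 317 higher and 443 lower for common limb over sham jejunum. Log2 ratios of common limb over sham jejunum were -0.79 for Slc2a1, -0.0930 for Reg3b, -0.29 for Lypd8, -0.0039 for Ca4, -1.21 for Gmds, -4.11 for Mgst1, 1.05 for Cd7, 5.08 for Cyp1a1, 1.62 for Bmp2, 2.82 for Ccl5, 1.98 for Ifitm1, 0.58 for Sqstm1, 1.27 for Slc2a6, 0.64 for Hmgcs1, 0.27 for Pcsk9, -1.04 for Dhcr7, 0.56 for Cd44, -1.16 for Pdia6, -1.02 for Sdf2l1, -1.10 for pentose phosphate pathway, -0.99 for TCA cycle and oxidative phosphorylation, 0.61 for insulin and growth factor signalling, 0.48 for amino acid and peptide transport, 0.72 for cholesterol synthesis, 0.21 for crypt stem cell and -0.31 for endoplasmic reticulum stress. With totals without the 20 most abundant genes, the counts of genes at least 2-fold apart were 106 lower for common limb over sham ileum and 564 higher for sham ileum over sham jejunum. Log2 ratios of alimentary limb over sham jejunum were -0.0887 for Prkcz. Under the stricter cell filter, log2 ratios of alimentary limb over sham jejunum were -0.53 for Slc2a1 and 0.0908 for dissociation and heat shock, and log2 ratios of common limb over sham ileum were 0.54 for Pcsk9, 0.17 for Cd44 and 0.0765 for insulin and growth factor signalling. Log2 ratios of sham ileum over sham jejunum were -0.18 for crypt stem cell. Shares were 54.0% T, NK or innate lymphoid-like and 20.3% enterocyte-like in the sham jejunum, 93.8% T, NK or innate lymphoid-like and 1.37% enterocyte-like in the sham ileum, 45.4% T, NK or innate lymphoid-like and 19.5% enterocyte-like in the alimentary limb and 55.0% T, NK or innate lymphoid-like and 33.3% enterocyte-like in the common limb. With TMM, log2 ratios of alimentary limb over sham jejunum were -0.0365 for Slc2a1, 0.0013 for Prkci and -0.25 for Prkcz. Over all epithelial-like cells, log2 ratios of common limb over sham ileum were 0.19 for Slc2a1, and log2 ratios of alimentary limb over sham jejunum were 0.11 for dissociation and heat shock. Without one-library clusters, log2 ratios of common limb over sham ileum were 0.48 for Slc2a1. With each library clustered on its own, shares were 37.0% T, NK or innate lymphoid-like and 41.3% enterocyte-like in the sham jejunum, 79.9% T, NK or innate lymphoid-like in the sham ileum, 41.4% enterocyte-like in the alimentary limb and 50.2% enterocyte-like in the common limb. At Leiden resolution 0.5, shares were 41.2% enterocyte-like in the sham jejunum and 26.4% enterocyte-like in the alimentary limb. With all deposited barcodes, shares were 82.9% T, NK or innate lymphoid-like in the sham ileum and 22.8% T, NK or innate lymphoid-like and 45.2% enterocyte-like in the alimentary limb. With doublet calls kept in, shares were 83.1% T, NK or innate lymphoid-like in the sham ileum and 22.8% T, NK or innate lymphoid-like and 45.1% enterocyte-like in the alimentary limb. At Leiden resolution 2, shares were 41.7% enterocyte-like in the alimentary limb.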

Other observations

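The values in this part were picked from other cell classes after they had been seen, and no test was run on them. In T, NK or innate lymphoid-like cells the alimentary limb stood close to sham jejunum, with 11 genes at 50 CPM or more at least 2-fold higher and 37 at least 2-fold lower. The transcription factors Runx1 and Maf were 6.28-fold and 2.53-fold higher and the inhibitory receptor Lag3 3.33-fold higher, while the granzymes Gzmb and Gzmbl1 were 4.54-fold and 5.12-fold lower. The class was made up of different clusters in the 2 libraries, with cluster 22, which leads with granzyme genes, holding 248 cells of sham jejunum and 58 of the alimentary limb, so these ratios do not separate cell make-up from expression within a cell type. Cholesterol synthesis genes were higher in 10 of 14 members and lower in 0, with a median log2 ratio of 0.76. Gip, a hormone of enteroendocrine cells, was 94.2-fold lower in these lymphoid-like cells, and enterocyte markers stood at 5798 CPM in them in the alimentary limb and at 13292 CPM in sham jejunum, so RNA of other cells was present in the class. In goblet-like cells Mptx1, a mucosal pentraxin, had 672 UMIs in the alimentary limb and 0 in sham jejunum, at least 91.6-fold higher, and the chemokine Ccl4 was 3.88-fold higher. MHC class II genes were lower in 4 of 4 measured members there, with RT1-Db1 5.78-fold, RT1-Da 5.37-fold and RT1-Ba 5.31-fold lower. Bcl2a1 was 9.01-fold lower on 19 against 70 UMIs. The direction of the class II genes was opposite to that in enterocyte-like cells. Whether RNA of immune cells in the goblet-like class made this difference was not tested. The goblet-like class held 298 cells of the alimentary limb and 95 of sham jejunum.

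Lymphoid-like cells of the common limb and the sham ileum stood further apart, with 248 genes at least 2-fold higher and 167 at least 2-fold lower. Cd200, an immune-inhibitory surface protein, was 42.9-fold higher, Runx1 22.0-fold and the chemokine Cxcl11 21.2-fold higher, while the cytokine Il4 was 36.3-fold lower. Here too the class sat in different clusters, with 29.6%, 25.7%, 19.3% and 11.9% of the sham ileum cells in clusters 2, 7, 10 and 17 and 41.3%, 19.1% and 12.9% of the common limb cells in clusters 14, 9 and 12. Cluster 10, led by Il4, held 1258 cells of the sham ileum and 24 of the common limb, so these ratios compare different mixtures of lymphoid-like cells. MHC class II genes were higher in 5 of 6 members. Enterocyte markers stood at 5660 CPM in these cells of the common limb and at 794 CPM in those of the sham ileum, which held 6515 of the lymphoid-like cells against 2380. A cluster named erythrocyte-like by its markers had 3480 UMIs of the haemoglobin gene Hba-a1 in sham jejunum and 0 in the alimentary limb, so its cells from the alimentary limb were not red cells. Cluster 27, unnamed, had 241 cells from the alimentary limb, 18 from the common limb and 0 from either sham library.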
